A study of Mus musculus with 9 samples.

How the data were processed

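Polyadenylated RNA from 9 mouse brains (sham, ICH and ICH+P7C3-A20, 3 mice each) was made into stranded libraries and sequenced, per the labels' protocols. Reads were handled with cutadapt 1.9, HISAT2 2.0.4 and StringTie 1.3.4d, per the submitters' processing notes. The genome build, the strand setting and the step that made the count columns are not given in the sources used here. The authors deposited 1 table of 35112 Ensembl genes with FPKM values (fragments scaled by transcript length and library total, per the file headers) and whole-number estimated counts per library. In each library 95.98% to 96.8% of low single-transcript genes had a deposited estimated count equal to FPKM times transcript length times a constant, rounded up (tolerance 0.01). The counts are thus estimates from coverage and were used whole, so that rounding changed none. Libraries totalled 51537047 to 63324728 estimated counts. Of the genes, 34996 have IDs in GENCODE M21 (GRCm38) and 32009 the identical position and strand. 1033 genes are at 0 in all libraries.

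Because the table held counts, edgeR replaced limma on log2(FPKM + 1) as the main test, as foreseen for that case. edgeR 4.0.16 in R 4.3.3 kept genes by filterByExpr (minimum count 10, minimum total 15), scaled libraries by TMM and fitted a robust quasi-likelihood model of 3 group means over all 9 libraries (6 residual degrees of freedom). Genes were called two-sided at a Benjamini-Hochberg adjusted p under 0.05. CPM used TMM-scaled totals. Folds against a group at 0 used a floor of 3 counts over the group. Gene lists were tested with camera in limma 3.58.1 (preset correlation 0.01), adjusted over the lists of a comparison, with an estimated correlation (p given where it ends the call) and with fry. The 38 lists held markers of immune, glial, vascular and neuronal cells and genes of inflammation, stress, cell cycle and metabolism, among others. A sex-linked list was described only. Annotation terms in the table with 10 to 300 tested genes were tested one-sided with the hypergeometric distribution and Benjamini-Hochberg adjustment against 16197 annotated tested genes.

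Named genes were, per comparison, the 8 largest and 8 lowest log2 changes among called genes with a mean FPKM of at least 2 in a group, groups that do not overlap and a gene symbol other than a clone, model or pseudogene name. To these were added up to 4 members of each list with the smallest p, and Nampt, Hmox1, Gfap, Il1b, Tmem119 and Rbfox3. Some genes that the rule takes are not reported here. Groups, tests, lists, this rule and most alternatives were set before the data were examined, and those chosen later are named with the alternatives. Alternatives were other filters, scalings and pseudocounts, DESeq2 1.42.0, limma, array weights, the compared groups alone, a replicate block, and each library left out. Shared sequence was searched among transcripts with minimap2 2.31, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

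The fits were tested on simulated counts with known changes among 21900 genes. For ICH against sham, ICH+P7C3-A20 against ICH and ICH+P7C3-A20 against sham, 5.97%, 7.46% and 4.48% of genes changed 1.5-fold were recovered, 41.8%, 41.8% and 47.8% at 2-fold and 57.6%, 62.1% and 65.2% at 4-fold, and 2.56%, 6.98% and 8.51% of calls were false. A shifted list was called in each, with 0, 1 and 1 of the other lists. In these simulations changes of up to 4-fold were often missed. Whether group size or the few changed genes (67, 67 and 66 per fold and a list) set this was not tested.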

Results

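Polyadenylated RNA was sequenced from brains of wild-type C57BL/6 mice, 3 separate animals per group: sham-operated, intracerebral haemorrhage (ICH), and ICH given P7C3-A20. Bleeding brings haem, iron and blood-derived cells into brain tissue. P7C3-A20 is one of the aminopropyl carbazoles linked to Nampt, the rate-limiting enzyme of NAD salvage. Brains were taken at 72 hours, and the labels give neither region nor dose. Replicates 1, 2 and 3 held 58048109, 56499987 and 63324728 estimated counts in sham, 56512348, 54441757 and 54700105 in ICH and 51537047, 59067945 and 55722322 in ICH+P7C3-A20. In a single library 3 counts equal 0.0474 to 0.0582 CPM, the depth-scaled count, a limit that covers counting error only. Libraries are named by group and replicate (ICH 2). CPM are mean ± SD (n = 3), and log2 changes ± an error, their size over the root of edgeR's F (all 9 libraries).

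Correlations between libraries across genes were 0.962 to 0.985 within groups and 0.891 to 0.968 between groups. The first principal component held 58.2% of the variance and placed sham at -38.7 to -31.3, ICH at 35.5 to 44.0 and ICH+P7C3-A20 1, 2 and 3 at -20.4, 7.38 and 0.772. ICH+P7C3-A20 1 stood apart from its group, with cortical neuron genes 1.64 above the sham mean on the log2 scale (0.72 and 0.93 in ICH+P7C3-A20 2 and 3) and oligodendrocyte genes at -1.01. Sham 3 had thalamic and hypothalamic genes at -2.05, against 0.40 and 1.66 in sham 1 and 2. Choroid plexus genes ranged from -1.58 to 3.19. Mitochondrially encoded transcripts, a sign of RNA quality, took 9.14% to 18.5% of counts, under 12% in sham 3, ICH 3 and ICH+P7C3-A20 2. Of 5 sex-linked genes, edgeR and DESeq2 called 0 in each comparison, with 1, 0 and 0 at an unadjusted p under 0.05 (1 was called lower in ICH without sham 2).

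Comparing ICH with sham asked how the haemorrhage altered brain transcripts. Most genes of the haem, inflammation, reactive astrocyte and cell cycle lists rose, and most pan-neuronal and striatal neuron genes fell. Hmox1, the enzyme that opens the haem ring, went from 5.24 ± 1.46 CPM in sham to 1087 ± 157 CPM in ICH, 208-fold higher (log2 change 7.70 ± 0.39, edgeR adjusted p = 4.95e-06). The astrocyte filament gene Gfap went from 123 ± 31.6 CPM in sham to 3106 ± 368 CPM in ICH, 25.3-fold higher (log2 change 4.66 ± 0.28, edgeR adjusted p = 6.31e-06). The neuronal nuclear gene Rbfox3 went from 197 ± 26.7 CPM in sham to 126 ± 9.90 CPM in ICH, 1.57-fold lower (log2 change -0.65 ± 0.15, edgeR adjusted p = 0.0109). edgeR called 5701 of 21900 tested genes, 3418 higher and 2283 lower (60.0% higher), 2384 of them changed at least 2-fold. Groups did not overlap for 9227 genes (42.1%, by chance 10%), 5639 of them called. With quantile-normalized FPKM 2499 were higher and 3300 lower (43.1% higher), and the median log2 change of all genes was -0.10. edgeR called 4273 (2765 higher, 1508 lower) without sham 1, 4190 (2716 higher, 1474 lower) without ICH 1, 4079 (2725 higher, 1354 lower) without ICH 2 and 4075 (2701 higher, 1374 lower) without ICH 3. Other genes fixed in advance had log2 changes of 4.98 ± 0.98 for Il1b, 1.84 ± 0.21 for Tmem119 and 0.33 ± 0.10 for Nampt (edgeR adjusted p 0.00389, 1.13e-04 and 0.0267). Il1b encodes interleukin-1 beta and Tmem119 marks resident microglia. The deposited positions were Hmox1 (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589), Gfap (ENSMUSG00000020932, chromosome 11, 102887336 to 102897200), Rbfox3 (ENSMUSG00000025576, chromosome 11, 118489762 to 118911597) and Nampt (ENSMUSG00000020572, chromosome 12, 32819545 to 32853349). By edgeR adjusted p, calls ended for Nampt without ICH 2 (0.0750), 3 (0.110) and sham 1 (0.0770), 2 (0.0533), 3 (0.0503). Where 1 library moved a fold over 1.5 times, the log2 change was 6.01 for Il1b without sham 1.

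**Figure D1:**
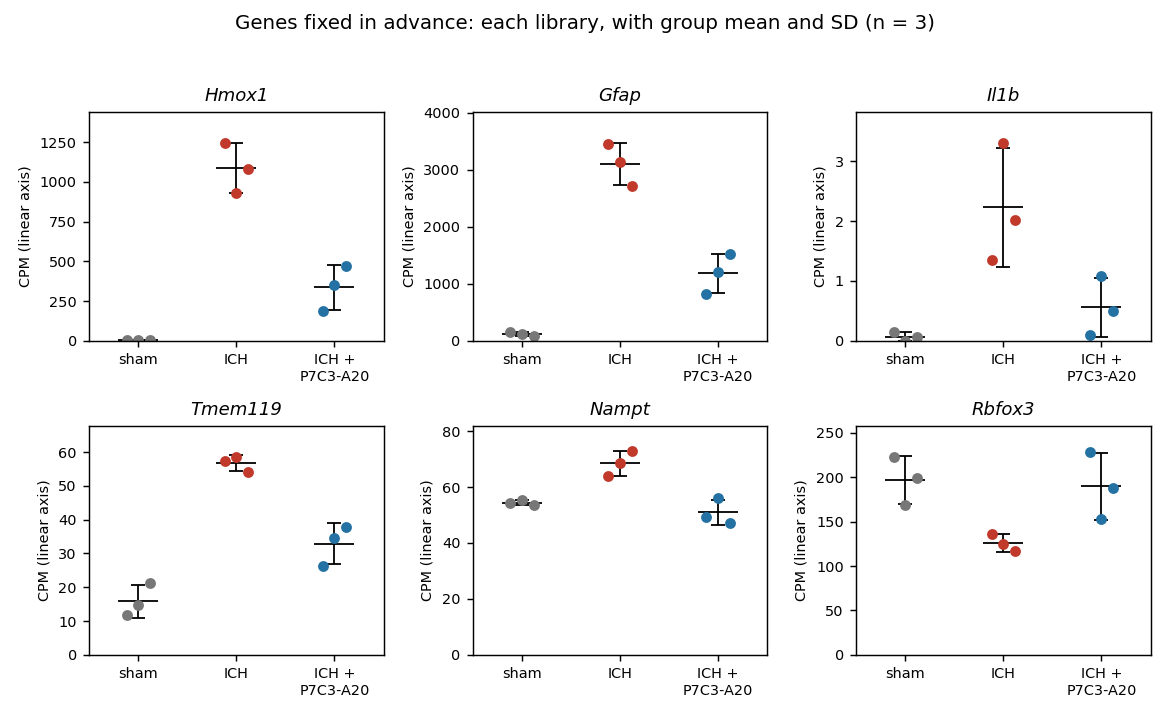
Expression in CPM on linear axes of the 6 genes fixed in advance, with a point per library, the group mean as a line and the SD as bars (n = 3 per group). Hmox1 averaged 5.24 in sham, 1087 in ICH and 337 in ICH+P7C3-A20.

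Among the largest rises, the apolipoprotein gene Apoc2 was at 0 in every sham library and reached 6.56 ± 1.68 CPM, at least 384-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 2.60e-05). Others were 8.81 ± 0.43 for Tgm1, 8.24 ± 0.70 for Acp5, 8.24 ± 1.09 for Mmp12, 7.80 ± 0.85 for Ccl4 and 7.46 ± 0.45 for Msr1 (edgeR adjusted p up to 7.79e-04), which encode a transglutaminase, an acid phosphatase, the macrophage elastase, a chemokine and a scavenger receptor. Kap, with 4 counts over the sham group, rose by 9.45 ± 2.16 on the log2 scale (edgeR adjusted p = 0.0149). The largest falls under the naming rule were -4.47 ± 1.06 for Oxt, -3.72 ± 0.98 for Lbhd2, -3.45 ± 0.27 for Hnrnpa3, -2.40 ± 0.67 for Gabrq, -2.10 ± 0.47 for Ngb, -1.88 ± 0.55 for Arhgap36, -1.75 ± 0.37 for Gpr101 and -1.70 ± 0.31 for Baiap3 (edgeR adjusted p up to 0.0316). Oxt encodes the hypothalamic peptide oxytocin, and thalamic and hypothalamic genes varied among sham libraries. Calls ended, by edgeR adjusted p, for Kap without sham 1 (0.0673), 2 (0.0589), 3 (0.0748), Oxt without ICH 1 (0.0606), 3 (0.0656), Lbhd2 without ICH 1 (0.0694), 2 (0.0720) and sham 1 (0.0554), Gabrq without ICH 1 (0.0709), 2 (0.0719), 3 (0.110) and sham 1 (0.0559), 2 (0.0750) and Arhgap36 without ICH 1 (0.0844), 2 (0.0536), 3 (0.120) and sham 1 (0.0638), 2 (0.111). Where 1 library moved a fold over 1.5 times, the log2 change was -1.25 for Arhgap36 without sham 2, 7.18 for Ccl4 without sham 3, 8.82 for Kap without sham 3, -4.34 for Lbhd2 without ICH 3, 7.59 for Mmp12 without sham 3, -5.10 for Oxt without ICH 2 and -3.55 for Oxt without sham 2. The 4 sham counts of Acp5, Ccl4 and Kap lay in sham 3, sham 2 and sham 2, without which sham was at 0 and those fitted changes (11.69, 11.32 and 12.97) are no bounds.

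Most genes of the immune and haem lists rose after ICH. Of 21 cytokine and chemokine genes, 16 rose (17 higher adjusted over the list alone), median log2 change 4.53 (camera adjusted p = 7.93e-19), such as 6.77 ± 0.42 for Ccl2, 5.22 ± 0.39 for Cxcl10 and 3.54 ± 0.24 for Cxcl16. With members at 0 in sham at their bound that median was 4.42. Of 14 complement genes, 12 rose (13 higher adjusted over the list alone), median log2 change 3.11 (camera adjusted p = 1.11e-25), such as 3.21 ± 0.22 for C1qa and 4.55 ± 0.29 for C3ar1. Of 19 interferon response genes, 18 rose (18 higher adjusted over the list alone), median log2 change 1.39 (camera adjusted p = 1.16e-08, adjusted p = 0.266 with an estimated correlation), such as 3.30 ± 0.37 for Mx1 and 1.31 ± 0.19 for Ifit2. Of 11 inflammasome and pyroptosis genes, 10 rose (10 higher adjusted over the list alone), median log2 change 2.33 (camera adjusted p = 1.68e-09, adjusted p = 0.0827 with an estimated correlation), such as 2.40 ± 0.21 for Pycard and 2.97 ± 0.33 for Nlrp3. Of 11 MHC class I presentation genes, 11 rose (11 higher adjusted over the list alone), median log2 change 1.95 (camera adjusted p = 9.08e-11, adjusted p = 0.0989 with an estimated correlation), such as 1.95 ± 0.20 for Tap1 and 2.12 ± 0.22 for H2-D1. Of 7 MHC class II presentation genes, 7 rose (7 higher adjusted over the list alone), median log2 change 3.91 (camera adjusted p = 7.38e-09), such as 4.29 ± 0.38 for H2-Aa and 3.91 ± 0.33 for H2-Eb1. Of 20 haem and iron handling genes, 14 rose and 2 fell (15 higher and 2 lower adjusted over the list alone), median log2 change 1.41 (camera adjusted p = 1.82e-10), such as 4.36 ± 0.24 for Slc11a1 and 1.81 ± 0.15 for Cp. For haem genes, lower calls were 1 without sham 1 and 3 and ICH 1 and 3. The named examples had edgeR adjusted p up to 6.60e-04.

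Most markers of microglia, monocytes and macrophages rose. Of 13 homeostatic microglia markers, 12 rose (13 higher adjusted over the list alone), median log2 change 1.84 (camera adjusted p = 2.24e-19), such as 3.72 ± 0.24 for Fcrls. Of 20 disease-associated microglia markers, 20 rose (20 higher adjusted over the list alone), median log2 change 2.89 (camera adjusted p = 2.06e-42), such as 6.46 ± 0.36 for Gpnmb and 4.65 ± 0.29 for Itgax. Of 15 monocyte and macrophage markers, 15 rose (15 higher adjusted over the list alone), median log2 change 4.70 (camera adjusted p = 6.34e-22), such as 5.21 ± 0.30 for Lyz2 and 7.21 ± 0.44 for Arg1. Of 10 neutrophil markers, 5 rose (7 higher adjusted over the list alone), median log2 change 1.94 (camera adjusted p = 0.00219, adjusted p = 0.162 with an estimated correlation), such as 2.52 ± 0.26 for Csf3r and 7.13 ± 0.94 for Mmp8. For neutrophil markers, higher calls were 3 without ICH 2. The neutrophil receptor gene Cxcr2 was at 0 in sham and at least 63.02-fold higher in ICH, or 17.9-fold without ICH 2 (edgeR adjusted p = 0.00597). Where 1 library moved a fold over 1.5 times, the log2 change was 3.01 for Hba-a2 without sham 2. The 4 sham counts of Mmp8 lay in sham 3, without which sham was at 0 and that fitted change (10.57) is no bound. Of 8 lymphocyte markers, 1 rose and 1 fell (1 higher and 1 lower adjusted over the list alone), median log2 change 1.26 (camera adjusted p = 0.698). For lymphocyte markers, higher calls were 2 without sham 3 and ICH 3, and 0 without ICH 1, lower calls were 0 without sham 1 and 3 and ICH 2 and 3. Of 8 red blood cell markers, 4 rose and 1 fell (4 higher and 1 lower adjusted over the list alone), median log2 change 1.83 (camera adjusted p = 0.127), such as 2.25 ± 0.51 for Hba-a2 and 2.11 ± 0.50 for Hba-a1. For red blood cell markers, camera called the list without ICH 1 (median 2.07, adjusted p = 0.0492) and sham 2 (median 2.30, adjusted p = 0.0332), lower calls were 0 without ICH 1 and 2. The examples had edgeR adjusted p up to 0.0113.

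Most reactive astrocyte, endothelial, mural cell and cell cycle genes rose. Of 20 reactive astrocyte genes, 20 rose (20 higher adjusted over the list alone), median log2 change 3.67 (camera adjusted p = 5.14e-46), such as 6.49 ± 0.31 for Timp1 and 3.37 ± 0.18 for S1pr3. Of 13 homeostatic astrocyte markers, 5 rose (5 higher adjusted over the list alone), median log2 change 0.20 (camera adjusted p = 0.0389, adjusted p = 0.444 with an estimated correlation), such as 1.72 ± 0.18 for Aqp4. For homeostatic astrocyte markers, the camera call ended without ICH 2 (median 0.16, adjusted p = 0.113) and sham 3 (median 0.27, adjusted p = 0.0565), lower calls were 1 without sham 3. Of 15 endothelial and barrier genes, 12 rose (14 higher adjusted over the list alone), median log2 change 0.86 (camera adjusted p = 3.08e-08, adjusted p = 0.0864 with an estimated correlation), such as 1.59 ± 0.16 for Pecam1. Of 15 fibroblast, mural cell and matrix genes, 10 rose and 1 fell (13 higher and 1 lower adjusted over the list alone), median log2 change 1.13 (camera adjusted p = 9.52e-08, adjusted p = 0.0559 with an estimated correlation), such as 2.10 ± 0.15 for Col4a1. For fibroblast genes, lower calls were 0 without sham 1 and ICH 1 to 3. Of 10 oligodendrocyte precursor markers, 5 rose (6 higher adjusted over the list alone), median log2 change 0.55 (camera adjusted p = 0.00752, adjusted p = 0.266 with an estimated correlation), such as 1.12 ± 0.12 for Cspg4. Of 23 cell cycle genes, 23 rose (23 higher adjusted over the list alone), median log2 change 3.56 (camera adjusted p = 3.32e-41), such as 3.02 ± 0.22 for Plk1 and 3.84 ± 0.27 for Tpx2. Of 22 apoptosis genes, 16 rose (17 higher and 1 lower adjusted over the list alone), median log2 change 0.85 (camera adjusted p = 1.33e-08), such as 1.87 ± 0.13 for Cdkn1a. For apoptosis, lower calls were 1 without sham 2. Of 18 antioxidant and ferroptosis genes, 8 rose and 2 fell (8 higher and 2 lower adjusted over the list alone), median log2 change 0.45 (camera adjusted p = 6.80e-04, adjusted p = 0.0864 with an estimated correlation), such as 2.06 ± 0.17 for Mt2 and 1.82 ± 0.19 for Nfe2l2. For antioxidant genes, lower calls were 1 without sham 1 and 2 and ICH 2 and 3, and 0 without ICH 1. The named examples had edgeR adjusted p up to 8.51e-05.

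Most pan-neuronal and striatal neuron genes fell in ICH. Of 18 pan-neuronal and glutamatergic genes, 12 fell (13 lower adjusted over the list alone), median log2 change -0.64 (camera adjusted p = 3.32e-06, adjusted p = 0.242 with an estimated correlation), such as -0.77 ± 0.14 for Grin1 and -0.63 ± 0.11 for Eno2. For pan-neuronal genes, lower calls were 7 without ICH 1 and 3. Of 15 striatal projection neuron genes, 13 fell (14 lower adjusted over the list alone), median log2 change -0.78 (camera adjusted p = 5.47e-07, adjusted p = 0.266 with an estimated correlation), such as -1.13 ± 0.16 for Tac1 and -0.96 ± 0.19 for Drd1. For striatal projection neuron genes, lower calls were 8 without sham 3 and ICH 1, and 5 without ICH 2, and 6 without ICH 3. Of 9 GABAergic interneuron genes, 3 fell (4 lower adjusted over the list alone), median log2 change -0.37 (camera adjusted p = 0.01001, adjusted p = 0.266 with an estimated correlation), such as -0.92 ± 0.11 for Slc32a1 and -0.81 ± 0.13 for Gad1. For GABAergic interneuron genes, the median was -0.61 without ICH 1 and -0.69 without ICH 2, higher calls were 1 without sham 2. Of 11 cortical neuron genes, 2 fell (2 lower adjusted over the list alone), median log2 change -0.18 (camera adjusted p = 0.333). For cortical neuron genes, higher calls were 1 without sham 3, lower calls were 0 without sham 1 and ICH 1 and 3, and 1 without sham 3 and ICH 2. Of 13 thalamic and hypothalamic genes, 1 fell (1 lower adjusted over the list alone), median log2 change -0.62 (camera adjusted p = 0.195). For thalamic genes, camera called the list without sham 3 (median -1.15, adjusted p = 7.58e-04), lower calls were 5 without sham 3, and 0 without ICH 1 and 3. Of 17 cholesterol synthesis genes, 10 fell (10 lower adjusted over the list alone), median log2 change -0.35 (camera adjusted p = 4.55e-04, adjusted p = 0.266 with an estimated correlation), such as -0.72 ± 0.12 for Insig1. For cholesterol synthesis, lower calls were 6 without sham 1 and 3, and 4 without sham 2, and 5 without ICH 1, and 2 without ICH 2 and 3. The examples had edgeR adjusted p up to 0.00453.

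Of 23 NAD metabolism genes, 6 rose and 2 fell (8 higher and 2 lower adjusted over the list alone), median log2 change 0.35 (camera adjusted p = 0.181). For NAD metabolism, higher calls were 3 without ICH 1, and 2 without ICH 2, lower calls were 0 without sham 1 and ICH 1 and 3, and 1 without sham 2 and 3 and ICH 2. Of 12 heat shock genes, 5 rose and 2 fell (5 higher and 4 lower adjusted over the list alone), median log2 change 0.17 (camera adjusted p = 0.155). For heat shock, camera called the list without sham 2 (median 0.18, adjusted p = 0.0336), lower calls were 1 without sham 2 and 3 and ICH 1 to 3. Of 16 immediate early genes, 4 rose and 5 fell (4 higher and 6 lower adjusted over the list alone), median log2 change -0.37 (camera adjusted p = 0.513). For immediate early genes, camera called the list without sham 1 (median -0.58, adjusted p = 0.0102). Of 14 oligodendrocyte and myelin genes, 1 rose (0 higher adjusted over the list alone), median log2 change 0.17 (camera adjusted p = 0.644). For oligodendrocyte genes, higher calls were 0 without sham 1 and 3 and ICH 1 and 3. Of 15 neurogenesis genes, 3 rose and 2 fell (4 higher and 4 lower adjusted over the list alone), median log2 change -0.06 (camera adjusted p = 0.897). For neurogenesis, lower calls were 1 without sham 1 and 2 and ICH 2 and 3, and 4 without sham 3. Of 12 neurotrophic factor genes, 2 fell (2 lower adjusted over the list alone), median log2 change -0.17 (camera adjusted p = 0.155). For neurotrophic factor genes, lower calls were 1 without ICH 2 and 3. Of 24 oxidative phosphorylation genes, edgeR called 0 (0 adjusted over the list alone, 4 at unadjusted p under 0.05, 3 by DESeq2), median log2 change -0.18 (camera adjusted p = 0.0847). For oxidative phosphorylation, camera called the list without ICH 3 (median -0.23, adjusted p = 0.0132) and sham 1 (median -0.24, adjusted p = 0.00689). Of 13 mitochondrially encoded genes, edgeR called 0 (0 adjusted over the list alone, 0 at unadjusted p under 0.05, 0 by DESeq2), median log2 change -0.20 (camera adjusted p = 0.404). Of 12 choroid plexus genes, edgeR called 0 (0 adjusted over the list alone, 1 at unadjusted p under 0.05, 1 by DESeq2), median log2 change 1.91 (camera adjusted p = 0.358). For choroid plexus, camera called the list without ICH 2 (median 2.47, adjusted p = 0.00337), higher calls were 1 without sham 2, and 2 without ICH 2. Of 9 ependymal genes, edgeR called 0 (0 adjusted over the list alone, 1 at unadjusted p under 0.05, 1 by DESeq2), median log2 change 0.29 (camera adjusted p = 0.809). For ependymal genes, higher calls were 1 without sham 1. Camera called 23 of 37 lists, 19 up and 4 down, 10 of them also with an estimated correlation, and fry, which does not compare a list with other genes, called 27. Of 4115 annotation terms, 675 were enriched among higher genes, led by inflammatory response (143 of 281 genes, hypergeometric adjusted p = 6.28e-29), and 291 among lower genes, led by postsynaptic membrane (91 of 197 genes, hypergeometric adjusted p = 2.70e-26).

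**Figure D2:**
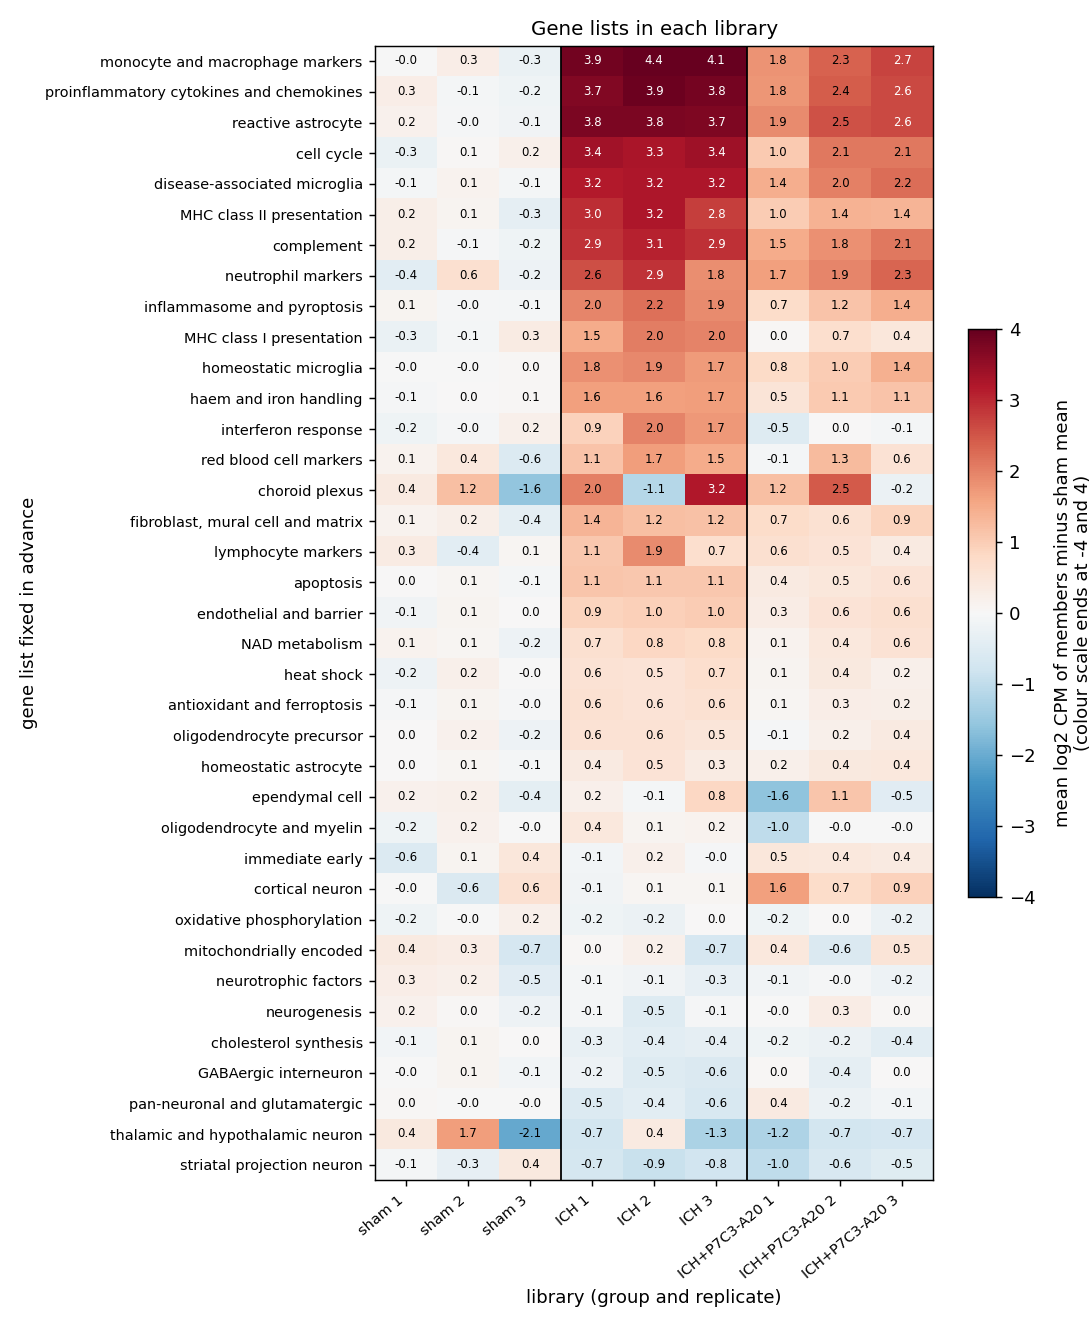
Mean log2 CPM of the members of each of 37 gene lists in each library, as the difference from the mean of the sham libraries (colour, with the value printed in each cell). Monocyte and macrophage markers lie at 3.86 to 4.45 in ICH and 1.78 to 2.70 in ICH+P7C3-A20.

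Comparing ICH+P7C3-A20 with ICH asked what the compound changed after the haemorrhage. Most interferon response, antigen presentation, macrophage, reactive astrocyte and cell cycle genes fell with P7C3-A20, and a smaller set of genes was higher. Hmox1 went from 1087 ± 157 CPM in ICH to 337 ± 141 CPM in ICH+P7C3-A20, 3.23-fold lower (log2 change -1.69 ± 0.30, edgeR adjusted p = 0.00974). Gfap went from 3106 ± 368 CPM in ICH to 1183 ± 348 CPM in ICH+P7C3-A20, 2.63-fold lower (log2 change -1.39 ± 0.25, edgeR adjusted p = 0.00974). The interferon regulatory factor gene Irf7 went from 40.02 ± 16.4 CPM in ICH to 8.16 ± 2.76 CPM in ICH+P7C3-A20, 4.90-fold lower (log2 change -2.29 ± 0.34, edgeR adjusted p = 0.00684). edgeR called 1914 of 21900 tested genes, 590 higher and 1324 lower (30.8% higher), 817 of them changed at least 2-fold. Groups did not overlap for 7353 genes (33.6%, by chance 10%), 1914 of them called. With quantile-normalized FPKM 1043 were higher and 1472 lower (41.5% higher). With limma on FPKM 258 were higher and 1240 lower (17.2% higher). With DESeq2 1355 were higher and 2177 lower (38.4% higher). edgeR called 683 (86 higher, 597 lower) without ICH 1, 571 (106 higher, 465 lower) without ICH 2, 671 (79 higher, 592 lower) without ICH 3, 813 (130 higher, 683 lower) without ICH+P7C3-A20 1 and 1460 (364 higher, 1096 lower) without ICH+P7C3-A20 3. Genes fixed in advance had log2 changes of -0.43 ± 0.10 for Nampt, -0.79 ± 0.20 for Tmem119, 0.59 ± 0.15 for Rbfox3 and -1.96 ± 0.81 for Il1b (edgeR adjusted p 0.0229, 0.0376, 0.0407 and 0.165), the last not called. By edgeR adjusted p, calls ended for Nampt without ICH 1 (0.0526), 2 (0.0860), 3 (0.101) and ICH+P7C3-A20 1 (0.0774), 3 (0.0712), Tmem119 without ICH 1 (0.114), 2 (0.119), 3 (0.0942) and ICH+P7C3-A20 1 (0.133), 2 (0.0599) and Rbfox3 without ICH 1 (0.0920), 2 (0.121), 3 (0.147) and ICH+P7C3-A20 1 (0.137), 3 (0.0830).

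The largest rises under the naming rule were 1.896 ± 0.44 for Scube1, 1.78 ± 0.45 for Vip, 1.69 ± 0.34 for Ccl21d, 1.69 ± 0.32 for Sidt1, 1.68 ± 0.40 for Nptxr, 1.67 ± 0.25 for Cbln2, 1.56 ± 0.27 for Nr4a1 and 1.52 ± 0.34 for Rasgrf2 on the log2 scale (edgeR adjusted p up to 0.0365). Cbln2 encodes a synapse organizer and Vip a peptide of interneurons. The largest falls under the naming rule were -2.95 ± 0.60 for Slfn4, -2.69 ± 0.38 for Zbp1, -2.64 ± 0.45 for Ccl7, -2.56 ± 0.49 for Ms4a4c, -2.50 ± 0.45 for Oasl1, -2.48 ± 0.53 for Phf11b, -2.42 ± 0.64 for Ly6c2 and -2.40 ± 0.59 for Plac8 (edgeR adjusted p up to 0.0423). Zbp1 is a nucleic acid sensor and Oasl1 an interferon-stimulated gene. Calls among the rises ended, by edgeR adjusted p, for Scube1 without ICH 1 (0.116), 2 (0.0596), 3 (0.119) and ICH+P7C3-A20 1 (0.0686), Vip without ICH 1 (0.137), 2 (0.0540), 3 (0.134) and ICH+P7C3-A20 1 (0.144), 3 (0.0623), Ccl21d without ICH 1 (0.0678), 2 (0.0565), Sidt1 without ICH 1 (0.0585), 3 (0.0567), Nptxr without ICH 1 (0.127), 3 (0.136) and ICH+P7C3-A20 1 (0.0717) and Rasgrf2 without ICH 1 (0.105), 2 (0.0624), 3 (0.104) and ICH+P7C3-A20 1 (0.0863). Among the falls they ended, by edgeR adjusted p, for Slfn4 without ICH 2 (0.0653), 3 (0.0562), Ms4a4c without ICH 2 (0.0568), Phf11b without ICH 2 (0.0796), 3 (0.0591), Ly6c2 without ICH 1 (0.0593), 2 (0.135), 3 (0.116) and ICH+P7C3-A20 1 (0.174), 2 (0.109) and Plac8 without ICH 1 (0.0552), 2 (0.120), 3 (0.0930) and ICH+P7C3-A20 1 (0.113), 3 (0.0774). Where 1 library moved a fold over 1.5 times, the log2 change was -3.06 for Ly6c2 without ICH+P7C3-A20 3, 1.04 for Nptxr without ICH+P7C3-A20 1, -3.21 for Phf11b without ICH+P7C3-A20 3 and 1.22 for Scube1 without ICH+P7C3-A20 1.

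Most interferon response and antigen presentation genes fell. Of 19 interferon response genes, 19 fell (19 lower adjusted over the list alone), median log2 change -2.02 (camera adjusted p = 2.46e-27, adjusted p = 0.0593 with an estimated correlation), such as -2.16 ± 0.26 for Oasl2, -2.02 ± 0.30 for Rsad2 and -1.33 ± 0.19 for Ifit2. Of 11 MHC class I presentation genes, 10 fell (11 lower adjusted over the list alone), median log2 change -1.48 (camera adjusted p = 1.92e-16, adjusted p = 0.0593 with an estimated correlation), such as -2.27 ± 0.30 for Nlrc5 and -1.59 ± 0.20 for Tap1. Of 7 MHC class II presentation genes, 5 fell (6 lower adjusted over the list alone), median log2 change -2.28 (camera adjusted p = 4.40e-09), such as -2.40 ± 0.34 for H2-Aa and -2.28 ± 0.30 for H2-Eb1. For MHC class II presentation, lower calls were 3 without ICH 2 and ICH+P7C3-A20 1. Of 21 cytokine and chemokine genes, 9 fell (12 lower adjusted over the list alone), median log2 change -1.75 (camera adjusted p = 4.52e-11), such as -2.20 ± 0.32 for Ccl2 and -2.27 ± 0.33 for Cxcl10. Of 14 complement genes, 8 fell (11 lower adjusted over the list alone), median log2 change -1.30 (camera adjusted p = 4.21e-13), such as -1.32 ± 0.20 for C1qa and -1.55 ± 0.25 for C3ar1. Of 11 inflammasome and pyroptosis genes, 4 fell (8 lower adjusted over the list alone), median log2 change -1.03 (camera adjusted p = 7.24e-06, adjusted p = 0.140 with an estimated correlation), such as -1.15 ± 0.20 for Pycard. For inflammasome genes, lower calls were 1 without ICH 1 and 2 and ICH+P7C3-A20 1, and 2 without ICH 3. Of 20 haem and iron handling genes, 8 fell (1 higher and 14 lower adjusted over the list alone), median log2 change -0.71 (camera adjusted p = 5.39e-08, adjusted p = 0.0593 with an estimated correlation), such as -1.61 ± 0.21 for Slc11a1 and -0.99 ± 0.15 for Cp. For haem genes, lower calls were 4 without ICH 1 and 2, and 3 without ICH 3. The named examples had edgeR adjusted p up to 0.00974.

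Most disease-associated microglia, macrophage, reactive astrocyte and cell cycle genes fell. Of 20 disease-associated microglia markers, 14 fell (19 lower adjusted over the list alone), median log2 change -1.27 (camera adjusted p = 1.27e-25), such as -2.08 ± 0.29 for Gpnmb and -1.901 ± 0.25 for Itgax. Of 13 homeostatic microglia markers, 6 fell (10 lower adjusted over the list alone), median log2 change -0.67 (camera adjusted p = 2.53e-09, adjusted p = 0.113 with an estimated correlation), such as -1.38 ± 0.22 for Fcrls and -1.20 ± 0.20 for Olfml3. For homeostatic microglia markers, lower calls were 3 without ICH 1, and 2 without ICH 2. Of 15 monocyte and macrophage markers, 11 fell (12 lower adjusted over the list alone), median log2 change -2.04 (camera adjusted p = 1.66e-14), such as -1.99 ± 0.26 for Lyz2 and -2.11 ± 0.33 for Arg1. For monocyte markers, lower calls were 7 without ICH 1 and 3, and 6 without ICH 2. Of 20 reactive astrocyte genes, 15 fell (19 lower adjusted over the list alone), median log2 change -1.43 (camera adjusted p = 1.50e-23), such as -1.84 ± 0.24 for Timp1 and -1.65 ± 0.17 for S1pr3. For reactive astrocyte genes, lower calls were 9 without ICH 1 and 2. Of 13 homeostatic astrocyte markers, 1 rose and 2 fell (1 higher and 2 lower adjusted over the list alone), median log2 change 0.01 (camera adjusted p = 0.940). Their mean was -0.07 and the test pointed down. For homeostatic astrocyte markers, higher calls were 0 without ICH 1 and 3 and ICH+P7C3-A20 1 and 3, lower calls were 1 without ICH 1 and 3 and ICH+P7C3-A20 3, and 0 without ICH 2. Of 23 cell cycle genes, 22 fell (23 lower adjusted over the list alone), median log2 change -1.50 (camera adjusted p = 8.13e-29, adjusted p = 0.0593 with an estimated correlation), such as -1.52 ± 0.21 for Plk1 and -1.21 ± 0.17 for Mcm6. For cell cycle, lower calls were 13 without ICH 1 and 2, and 12 without ICH 3. Of 22 apoptosis genes, 7 fell (14 lower adjusted over the list alone), median log2 change -0.56 (camera adjusted p = 9.33e-09), such as -1.07 ± 0.13 for Cdkn1a and -0.65 ± 0.09 for Mcl1. For apoptosis, lower calls were 4 without ICH 1, and 3 without ICH 2. Of 18 antioxidant and ferroptosis genes, 6 fell (8 lower adjusted over the list alone), median log2 change -0.30 (camera adjusted p = 4.72e-05, adjusted p = 0.0593 with an estimated correlation), such as -1.19 ± 0.16 for Mt2 and -1.01 ± 0.18 for Nfe2l2. For antioxidant genes, lower calls were 3 without ICH 1. The examples had edgeR adjusted p up to 0.0111.

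Over all genes, edgeR called 4 or fewer genes of each vascular, heat shock and oligodendrocyte lineage list, all lower, and no such list call held with an estimated correlation. DESeq2 called 8 endothelial and 5 oligodendrocyte precursor genes lower. Of 15 endothelial and barrier genes, 4 fell (8 lower adjusted over the list alone), median log2 change -0.42 (camera adjusted p = 5.29e-05, adjusted p = 0.170 with an estimated correlation). For endothelial genes, lower calls were 1 without ICH 1, and 0 without ICH 2, and 2 without ICH 3 and ICH+P7C3-A20 1. Of 15 fibroblast, mural cell and matrix genes, 4 fell (5 lower adjusted over the list alone), median log2 change -0.35 (camera adjusted p = 2.04e-04, adjusted p = 0.143 with an estimated correlation), such as -1.03 ± 0.14 for Col4a1 and -1.65 ± 0.28 for Tagln. For fibroblast genes, lower calls were 2 without ICH 2. Of 12 heat shock genes, 2 fell (4 lower adjusted over the list alone), median log2 change -0.23 (camera adjusted p = 0.0324, adjusted p = 0.426 with an estimated correlation), such as -1.11 ± 0.17 for Hspb8. For heat shock, the camera call ended without ICH 3 (median -0.19, adjusted p = 0.0854), ICH+P7C3-A20 1 (median -0.13, adjusted p = 0.0689) and ICH+P7C3-A20 3 (median -0.20, adjusted p = 0.120), the median was -0.37 without ICH+P7C3-A20 2, lower calls were 1 without ICH 1 to 3 and ICH+P7C3-A20 1 and 3. Of 14 oligodendrocyte and myelin genes, 1 fell (0 lower adjusted over the list alone), median log2 change -0.53 (camera adjusted p = 2.76e-04, adjusted p = 0.426 with an estimated correlation). For oligodendrocyte genes, the median was -0.25 without ICH+P7C3-A20 1, lower calls were 0 without ICH 1 to 3 and ICH+P7C3-A20 1, and 2 without ICH+P7C3-A20 2. Against the sham mean their scores were -1.01, -0.01 and -0.03 in ICH+P7C3-A20 1, 2 and 3. Of 10 oligodendrocyte precursor markers, 1 fell (6 lower adjusted over the list alone), median log2 change -0.46 (camera adjusted p = 0.00272, adjusted p = 0.217 with an estimated correlation), such as -0.71 ± 0.12 for Cspg4. For oligodendrocyte precursor markers, the median was -0.30 without ICH+P7C3-A20 1, lower calls were 2 without ICH+P7C3-A20 2. The named examples had edgeR adjusted p up to 0.00856. Neuronal lists were tested in the same way, and cortical neuron genes stood highest in ICH+P7C3-A20 1. Of 18 pan-neuronal and glutamatergic genes, 4 rose (15 higher adjusted over the list alone), median log2 change 0.61 (camera adjusted p = 1.68e-08, adjusted p = 0.153 with an estimated correlation). For pan-neuronal genes, the median was 0.36 without ICH+P7C3-A20 1, higher calls were 0 without ICH 1 to 3 and ICH+P7C3-A20 1, and 7 without ICH+P7C3-A20 2, and 2 without ICH+P7C3-A20 3. Of 11 cortical neuron genes, 3 rose (6 higher adjusted over the list alone), median log2 change 1.29 (camera adjusted p = 5.45e-06, adjusted p = 0.114 with an estimated correlation). For cortical neuron genes, higher calls were 0 without ICH 1 to 3 and ICH+P7C3-A20 1. Of 9 GABAergic interneuron genes, 1 rose (1 higher adjusted over the list alone), median log2 change 0.23 (camera adjusted p = 0.0585). For GABAergic interneuron genes, camera called the list without ICH 1 (median 0.44, adjusted p = 0.00253) and ICH+P7C3-A20 2 (median 0.30, adjusted p = 0.00571), higher calls were 0 without ICH 1 to 3 and ICH+P7C3-A20 1 and 3. Of 15 striatal projection neuron genes, edgeR called 0 (0 adjusted over the list alone, 1 at unadjusted p under 0.05, 0 by DESeq2), median log2 change 0.08 (camera adjusted p = 0.301). For striatal projection neuron genes, camera called the list without ICH+P7C3-A20 1 (median 0.24, adjusted p = 0.0113). Of 13 thalamic and hypothalamic genes, edgeR called 0 (0 adjusted over the list alone, 1 at unadjusted p under 0.05, 0 by DESeq2), median log2 change 0.01 (camera adjusted p = 0.940). Their mean was -0.73 and the test pointed up.

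Of 16 immediate early genes, 3 rose and 2 fell (7 higher and 2 lower adjusted over the list alone), median log2 change 0.44 (camera adjusted p = 0.0202, adjusted p = 0.452 with an estimated correlation). For immediate early genes, the camera call ended without ICH 1 (median 0.43, adjusted p = 0.0646) and ICH+P7C3-A20 2 (median 0.54, adjusted p = 0.0552), lower calls were 1 without ICH 2 and 3. Of 23 NAD metabolism genes, 1 fell (1 lower adjusted over the list alone), median log2 change -0.23 (camera adjusted p = 0.196). For NAD metabolism, higher calls were 1 without ICH+P7C3-A20 2, lower calls were 0 without ICH 1 to 3 and ICH+P7C3-A20 1. Of 15 neurogenesis genes, 1 rose and 1 fell (4 higher and 1 lower adjusted over the list alone), median log2 change 0.25 (camera adjusted p = 0.217). For neurogenesis, higher calls were 0 without ICH 1 to 3 and ICH+P7C3-A20 1, and 2 without ICH+P7C3-A20 2, lower calls were 0 without ICH 2 and 3, and 2 without ICH+P7C3-A20 2. Of 12 neurotrophic factor genes, 1 rose (1 higher adjusted over the list alone), median log2 change 0.07 (camera adjusted p = 0.188). For neurotrophic factor genes, higher calls were 0 without ICH 1 to 3 and ICH+P7C3-A20 1 and 3. Of 10 neutrophil markers, 1 fell (1 lower adjusted over the list alone), median log2 change -0.76 (camera adjusted p = 0.173). For neutrophil markers, lower calls were 0 without ICH 1 and 2 and ICH+P7C3-A20 1 and 2, and 2 without ICH+P7C3-A20 3. Of 8 lymphocyte markers, edgeR called 0 (0 adjusted over the list alone, 0 at unadjusted p under 0.05, 0 by DESeq2), median log2 change -0.55 (camera adjusted p = 0.392). Of 8 red blood cell markers, edgeR called 0 (5 adjusted over the list alone, 5 at unadjusted p under 0.05, 5 by DESeq2), median log2 change -1.29 (camera adjusted p = 0.123). For red blood cell markers, camera called the list without ICH 1 (median -1.53, adjusted p = 0.0351) and ICH+P7C3-A20 2 (median -1.50, adjusted p = 0.0403), lower calls were 1 without ICH+P7C3-A20 2. Of 24 oxidative phosphorylation genes, edgeR called 0 (0 adjusted over the list alone, 1 at unadjusted p under 0.05, 0 by DESeq2), median log2 change -0.02 (camera adjusted p = 0.925). Their mean was -0.01 and the test pointed up. Of 13 mitochondrially encoded genes, edgeR called 0 (0 adjusted over the list alone, 0 at unadjusted p under 0.05, 0 by DESeq2), median log2 change 0.34 (camera adjusted p = 0.123). For mitochondrially encoded genes, camera called the list without ICH 2 (median 0.54, adjusted p = 0.0134) and ICH+P7C3-A20 2 (median 0.66, adjusted p = 5.41e-04). Of 17 cholesterol synthesis genes, edgeR called 0 (0 adjusted over the list alone, 3 at unadjusted p under 0.05, 0 by DESeq2), median log2 change 0.08 (camera adjusted p = 0.166). For cholesterol synthesis, camera called the list without ICH+P7C3-A20 3 (median 0.13, adjusted p = 0.0271). Of 12 choroid plexus genes, edgeR called 0 (0 adjusted over the list alone, 0 at unadjusted p under 0.05, 0 by DESeq2), median log2 change -0.64 (camera adjusted p = 0.739). For choroid plexus, camera called the list without ICH 2 (median -1.19, adjusted p = 0.00438). Of 9 ependymal genes, edgeR called 0 (0 adjusted over the list alone, 1 at unadjusted p under 0.05, 0 by DESeq2), median log2 change -0.17 (camera adjusted p = 0.294). For ependymal genes, camera called the list without ICH+P7C3-A20 2 (median -1.21, adjusted p = 3.04e-04). In this comparison, camera called 22 of 37 lists, 3 up and 19 down, 7 of them also with an estimated correlation, and fry called 20. Of 4115 annotation terms, 113 were enriched among higher genes, led by postsynaptic membrane (27 of 197 genes, hypergeometric adjusted p = 1.16e-06), and 473 among lower genes, led by Epstein-Barr virus infection (66 of 188 genes, hypergeometric adjusted p = 9.28e-23).

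Genes altered by ICH were followed into ICH+P7C3-A20. Of the 5701 called, 98.2% had the opposite sign against ICH. Both contrasts use the same ICH libraries. Simulations with the ICH effect alone gave a median of 59.5% (highest 60.9%, 20 runs). Whether shifts shared by many genes give 98.2% was not tested. Of 3418 genes higher in ICH, 3352 moved back and 1298 were called lower, with a median log2 change of 1.27 and then -0.67. Of 2283 lower genes, 2244 moved back and 433 were called higher (-0.63, then 0.34). Independent lists would share 207 and 61.5 genes, and part of the excess may come from the shared ICH libraries. Simulated data with no effect called a median of 0 genes (highest 1) in ICH+P7C3-A20 against ICH, which fixes their overlap at 0. Across genes, which are not independent replicates, the covariance of log2 changes was -0.628 (-0.123 simulated with the ICH effect alone, -0.129 with no effect). Pearson's r was -0.667 (-0.195 and -0.502 simulated). With 1 ICH library held out for the change, and genes called on the remaining pair, the share was 94.7%, 96.4% and 95.8% for ICH 1, 2 and 3. Each ICH+P7C3-A20 library alone gave 96.04%, 95.9% and 94.5% (mean 95.5%, SD 0.845).

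Comparing ICH+P7C3-A20 with sham asked what remained altered with the compound. Most macrophage, reactive astrocyte and cell cycle genes were above sham, and fewer genes were below it. Hmox1 went from 5.24 ± 1.46 CPM in sham to 337 ± 141 CPM in ICH+P7C3-A20, 64.4-fold higher (log2 change 6.01 ± 0.36, edgeR adjusted p = 7.85e-05). Gfap went from 123 ± 31.6 CPM in sham to 1183 ± 348 CPM in ICH+P7C3-A20, 9.63-fold higher (log2 change 3.27 ± 0.26, edgeR adjusted p = 1.97e-04). Hnrnpa3, which encodes an RNA-binding protein and shares sequence with near-identical copies, went from 136 ± 7.72 CPM in sham to 10.5 ± 3.30 CPM in ICH+P7C3-A20, 12.9-fold lower (log2 change -3.69 ± 0.27, edgeR adjusted p = 1.63e-04). Summed with those copies (22 genes), counts changed by -0.716 ± 0.140 in log2 (standard error). The deposited position was Hnrnpa3 (ENSMUSG00000059005, chromosome 2, 75659261 to 75669407). edgeR called 1165 of 21900 tested genes, 1002 higher and 163 lower (86.0% higher), 718 of them changed at least 2-fold. Groups did not overlap for 4473 genes (20.4%, by chance 10%), 1152 of them called. With DESeq2 1558 were higher and 551 lower, with limma 385 and 23, with these groups alone 393 and 42. edgeR called 653 (609 higher, 44 lower) without sham 1, 774 (696 higher, 78 lower) without ICH+P7C3-A20 2 and 538 (496 higher, 42 lower) without ICH+P7C3-A20 3. Genes fixed in advance had log2 changes of 1.05 ± 0.20 for Tmem119, -0.10 ± 0.10 for Nampt, -0.06 ± 0.15 for Rbfox3 and 3.02 ± 0.95 for Il1b (edgeR adjusted p 0.0136, 0.684, 0.908 and 0.111), and of these Tmem119 alone was called. By edgeR adjusted p, calls ended for Tmem119 without ICH+P7C3-A20 3 (0.0664) and sham 2 (0.0517), and Il1b was called without ICH+P7C3-A20 1 (0.0330).

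Of 1002 genes higher than sham, 955 were also higher in ICH (independent lists 156), and of 163 lower genes 154 were lower in ICH (17.0). Part of the excess over independent lists may come from the shared sham libraries. Simulated groups with no effect called a median of 0 genes in ICH, which fixes their overlap at 0, and those with the ICH effect and no effect of P7C3-A20 shared a median of 3048 and 1901 (20 runs). Of 1324 genes lower than in ICH, 641 were still higher than sham (independent lists 60.6). These contrasts share the ICH+P7C3-A20 libraries, and as both simulations called a median of 0 genes against ICH, this overlap has no simulated reference. Besides Hmox1, the largest rises under the naming rule were 6.76 ± 0.40 for Tgm1, 6.04 ± 0.84 for Ccl4, 5.60 ± 0.41 for Lcn2, 5.22 ± 0.37 for Lilr4b, 5.10 ± 0.42 for Arg1, 5.03 ± 0.47 for Ch25h and 4.77 ± 0.32 for Lilrb4a on the log2 scale (edgeR adjusted p up to 0.00255). Lcn2 encodes the iron-scavenging lipocalin 2 and Arg1 arginase 1. Among the largest falls after Hnrnpa3 were -1.48 ± 0.25 for Ano2, -1.22 ± 0.23 for Rarb, -1.21 ± 0.19 for Sh3rf2, -1.18 ± 0.19 for Nexn, -0.98 ± 0.22 for Cd4 and -0.96 ± 0.21 for Ano3 (edgeR adjusted p up to 0.0267). Calls ended, by edgeR adjusted p, for Cd4 without ICH+P7C3-A20 1 (0.0571), 2 (0.0900) and sham 1 (0.0913), 3 (0.0631) and Ano3 without ICH+P7C3-A20 1 (0.0580), 2 (0.0678), 3 (0.0513) and sham 1 (0.0867), 3 (0.0556). Where 1 library moved a fold over 1.5 times, the log2 change was 5.42 for Ccl4 without sham 3 and 5.80 for Ch25h without sham 1. The 4 sham counts of Ccl4 lay in sham 2, without which sham was at 0 and that fitted change (9.57) is no bound.

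Some inflammatory genes were above sham. Of 19 interferon response genes, 1 fell (2 lower adjusted over the list alone), median log2 change -0.10 (camera adjusted p = 0.0442, adjusted p = 0.627 with an estimated correlation). For interferon response, the camera call ended without ICH+P7C3-A20 1 (median -0.03, adjusted p = 0.479) and sham 3 (median 0.01, adjusted p = 0.268), the median was -0.45 without ICH+P7C3-A20 2, -0.29 without ICH+P7C3-A20 3, -0.25 without sham 1 and -0.19 without sham 2, higher calls were 1 without sham 3, lower calls were 0 without sham 1 and 2 and ICH+P7C3-A20 1 to 3. Of 11 MHC class I presentation genes, edgeR called 0 (3 adjusted over the list alone, 5 at unadjusted p under 0.05, 1 by DESeq2), median log2 change 0.37 (camera adjusted p = 0.0305, adjusted p = 0.567 with an estimated correlation). For MHC class I presentation, the camera call ended without ICH+P7C3-A20 2 (median 0.33, adjusted p = 0.197), sham 1 (median 0.31, adjusted p = 0.172) and sham 2 (median 0.44, adjusted p = 0.0653), the median was 0.62 without sham 3, higher calls were 1 without sham 3 and ICH+P7C3-A20 1. Of 7 MHC class II presentation genes, 3 rose (5 higher adjusted over the list alone), median log2 change 1.60 (camera adjusted p = 1.33e-05, adjusted p = 0.0527 with an estimated correlation), such as 2.01 ± 0.36 for H2-Ab1. For MHC class II presentation, higher calls were 1 without ICH+P7C3-A20 3. Of 21 cytokine and chemokine genes, 11 rose (17 higher adjusted over the list alone), median log2 change 2.68 (camera adjusted p = 4.00e-22), such as 4.57 ± 0.39 for Ccl2 and 2.03 ± 0.23 for Cxcl16. For cytokine genes, higher calls were 7 without ICH+P7C3-A20 3. Tnf, at 0 in sham, was at least 28.9-fold higher (edgeR adjusted p = 9.34e-04). Of 14 complement genes, 10 rose (11 higher adjusted over the list alone), median log2 change 1.81 (camera adjusted p = 3.83e-30), such as 3.58 ± 0.32 for C5ar1 and 3.01 ± 0.27 for C3ar1. Of 11 inflammasome and pyroptosis genes, 6 rose (9 higher adjusted over the list alone), median log2 change 1.19 (camera adjusted p = 1.30e-08, adjusted p = 0.0967 with an estimated correlation), such as 2.21 ± 0.35 for Naip2 and 1.94 ± 0.32 for Nlrp3. For inflammasome genes, higher calls were 3 without ICH+P7C3-A20 3. Of 20 haem and iron handling genes, 6 rose (7 higher adjusted over the list alone), median log2 change 0.50 (camera adjusted p = 2.10e-08, adjusted p = 0.0704 with an estimated correlation), such as 2.75 ± 0.23 for Slc11a1. For haem genes, the median was 0.77 without ICH+P7C3-A20 1, higher calls were 10 without ICH+P7C3-A20 1. The examples had edgeR adjusted p up to 0.00906.

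Most microglia, macrophage, reactive astrocyte and cell cycle genes were above sham. Of 20 disease-associated microglia markers, 16 rose (18 higher adjusted over the list alone), median log2 change 1.67 (camera adjusted p = 1.19e-42), such as 4.38 ± 0.33 for Gpnmb. Of 13 homeostatic microglia markers, 11 rose (12 higher adjusted over the list alone), median log2 change 1.03 (camera adjusted p = 3.44e-20, adjusted p = 0.0559 with an estimated correlation), such as 2.34 ± 0.23 for Fcrls. For homeostatic microglia markers, higher calls were 7 without sham 1 and 2, and 6 without ICH+P7C3-A20 3. Of 15 monocyte and macrophage markers, 10 rose (12 higher adjusted over the list alone), median log2 change 2.19 (camera adjusted p = 6.81e-24), such as 3.22 ± 0.28 for Lyz2. For monocyte markers, higher calls were 6 without ICH+P7C3-A20 3. Of 10 neutrophil markers, 2 rose (5 higher adjusted over the list alone), median log2 change 1.81 (camera adjusted p = 5.01e-05, adjusted p = 0.0704 with an estimated correlation), such as 1.54 ± 0.25 for Csf3r. Of 20 reactive astrocyte genes, 16 rose (19 higher adjusted over the list alone), median log2 change 2.13 (camera adjusted p = 2.20e-56), such as 4.64 ± 0.29 for Timp1 and 4.26 ± 0.33 for Serpina3n. Of 13 homeostatic astrocyte markers, 2 rose (8 higher adjusted over the list alone), median log2 change 0.36 (camera adjusted p = 5.69e-04, adjusted p = 0.264 with an estimated correlation). For homeostatic astrocyte markers, higher calls were 0 without sham 1 and 2 and ICH+P7C3-A20 2 and 3, and 4 without ICH+P7C3-A20 1. Of 15 endothelial and barrier genes, 5 rose (8 higher adjusted over the list alone), median log2 change 0.44 (camera adjusted p = 1.24e-06, adjusted p = 0.134 with an estimated correlation). For endothelial genes, higher calls were 0 without sham 1 and ICH+P7C3-A20 3, and 3 without ICH+P7C3-A20 2. Of 15 fibroblast, mural cell and matrix genes, 4 rose (10 higher adjusted over the list alone), median log2 change 0.71 (camera adjusted p = 5.15e-07, adjusted p = 0.0704 with an estimated correlation), such as 1.08 ± 0.15 for Col4a1. For fibroblast genes, the median was 0.47 without sham 3, higher calls were 2 without sham 1 and ICH+P7C3-A20 3. Of 23 cell cycle genes, 20 rose (22 higher adjusted over the list alone), median log2 change 1.78 (camera adjusted p = 1.30e-35, adjusted p = 0.0704 with an estimated correlation), such as 2.27 ± 0.25 for Tpx2 and 2.93 ± 0.35 for Rrm2. Of 22 apoptosis genes, 4 rose (6 higher adjusted over the list alone), median log2 change 0.33 (camera adjusted p = 5.86e-04, adjusted p = 0.0688 with an estimated correlation), such as 0.80 ± 0.13 for Cdkn1a. The named examples had edgeR adjusted p up to 0.00554.

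Neuronal and oligodendrocyte lists were compared with sham next. Of 18 pan-neuronal and glutamatergic genes, edgeR called 0 (0 adjusted over the list alone, 5 at unadjusted p under 0.05, 3 by DESeq2), median log2 change -0.09 (camera adjusted p = 0.0903). For pan-neuronal genes, camera called the list without ICH+P7C3-A20 1 (median -0.32, adjusted p = 4.53e-04), higher calls were 1 without sham 3, lower calls were 1 without sham 3, and 3 without ICH+P7C3-A20 1. Of 15 striatal projection neuron genes, 4 fell (14 lower adjusted over the list alone), median log2 change -0.69 (camera adjusted p = 2.80e-13, adjusted p = 0.141 with an estimated correlation). For striatal projection neuron genes, lower calls were 7 without sham 2, and 2 without ICH+P7C3-A20 1 to 3. Of 9 GABAergic interneuron genes, 2 fell (2 higher and 3 lower adjusted over the list alone), median log2 change -0.32 (camera adjusted p = 0.0271, adjusted p = 0.430 with an estimated correlation). For GABAergic interneuron genes, the camera call ended without ICH+P7C3-A20 2 (median -0.21, adjusted p = 0.299) and sham 2 (median -0.14, adjusted p = 0.0885), higher calls were 1 without sham 3, and 2 without ICH+P7C3-A20 2, lower calls were 1 without sham 1 and 2 and ICH+P7C3-A20 2 and 3. Of 11 cortical neuron genes, edgeR called 0 (0 adjusted over the list alone, 4 at unadjusted p under 0.05, 1 by DESeq2), median log2 change 0.80 (camera adjusted p = 0.00298, adjusted p = 0.290 with an estimated correlation). For cortical neuron genes, the camera call ended without ICH+P7C3-A20 1 (median 0.44, adjusted p = 0.135), higher calls were 2 without sham 3. Of 13 thalamic and hypothalamic genes, edgeR called 0 (0 adjusted over the list alone, 0 at unadjusted p under 0.05, 0 by DESeq2), median log2 change -1.04 (camera adjusted p = 0.0204, adjusted p = 0.553 with an estimated correlation). For thalamic genes, the camera call ended without ICH+P7C3-A20 1 (median -0.80, adjusted p = 0.142) and sham 2 (median -0.55, adjusted p = 0.420), lower calls were 2 without sham 3. Of 14 oligodendrocyte and myelin genes, edgeR called 0 (0 adjusted over the list alone, 0 at unadjusted p under 0.05, 0 by DESeq2), median log2 change -0.35 (camera adjusted p = 0.00221, adjusted p = 0.553 with an estimated correlation). For oligodendrocyte genes, the camera call ended without ICH+P7C3-A20 1 (median -0.09, adjusted p = 0.479). Of 10 oligodendrocyte precursor markers, edgeR called 0 (2 adjusted over the list alone, 3 at unadjusted p under 0.05, 1 by DESeq2), median log2 change 0.20 (camera adjusted p = 0.240). For oligodendrocyte precursor markers, higher calls were 2 without ICH+P7C3-A20 1. Of 17 cholesterol synthesis genes, edgeR called 0 (2 adjusted over the list alone, 7 at unadjusted p under 0.05, 2 by DESeq2), median log2 change -0.31 (camera adjusted p = 1.36e-05, adjusted p = 0.213 with an estimated correlation). For cholesterol synthesis, lower calls were 1 without ICH+P7C3-A20 1 and 2. Of 24 oxidative phosphorylation genes, edgeR called 0 (0 adjusted over the list alone, 4 at unadjusted p under 0.05, 1 by DESeq2), median log2 change -0.17 (camera adjusted p = 0.00333, adjusted p = 0.609 with an estimated correlation). For oxidative phosphorylation, the camera call ended without sham 3 (median -0.04, adjusted p = 0.172). Of 13 mitochondrially encoded genes, edgeR called 0 (0 adjusted over the list alone, 0 at unadjusted p under 0.05, 0 by DESeq2), median log2 change 0.15 (camera adjusted p = 0.832). For mitochondrially encoded genes, camera called the list without ICH+P7C3-A20 2 (median 0.43, adjusted p = 0.0263).

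Of 23 NAD metabolism genes, 1 rose (1 higher adjusted over the list alone), median log2 change 0.14 (camera adjusted p = 0.349). Of 18 antioxidant and ferroptosis genes, 3 rose (3 higher adjusted over the list alone), median log2 change 0.10 (camera adjusted p = 0.196). For antioxidant genes, higher calls were 0 without sham 1 and ICH+P7C3-A20 3, and 1 without sham 3. Of 16 immediate early genes, 1 rose (3 higher adjusted over the list alone), median log2 change 0.19 (camera adjusted p = 0.177). For immediate early genes, camera called the list without sham 3 (median 0.41, adjusted p = 0.00318), higher calls were 0 without sham 1, and 3 without sham 3. Of 12 heat shock genes, 2 rose (3 higher adjusted over the list alone), median log2 change -0.04 (camera adjusted p = 0.832). Their mean was 0.21 and the test pointed up. For heat shock, higher calls were 1 without sham 1 and 3 and ICH+P7C3-A20 2 and 3. Of 15 neurogenesis genes, 1 rose (2 higher adjusted over the list alone), median log2 change 0.28 (camera adjusted p = 0.310). For neurogenesis, higher calls were 0 without sham 1 to 3 and ICH+P7C3-A20 2 and 3. Of 12 neurotrophic factor genes, edgeR called 0 (0 adjusted over the list alone, 3 at unadjusted p under 0.05, 1 by DESeq2), median log2 change 0.06 (camera adjusted p = 0.310). Their mean was -0.03 and the test pointed down. Of 8 lymphocyte markers, 1 fell (1 higher and 1 lower adjusted over the list alone), median log2 change 0.34 (camera adjusted p = 0.850). Their mean was 1.05 and the test pointed down. For lymphocyte markers, higher calls were 1 without sham 3 and ICH+P7C3-A20 1, lower calls were 0 without sham 1 and 3 and ICH+P7C3-A20 1 and 2. Of 8 red blood cell markers, edgeR called 0 (0 adjusted over the list alone, 0 at unadjusted p under 0.05, 0 by DESeq2), median log2 change 0.67 (camera adjusted p = 0.326). Of 12 choroid plexus genes, edgeR called 0 (0 adjusted over the list alone, 0 at unadjusted p under 0.05, 0 by DESeq2), median log2 change 1.22 (camera adjusted p = 0.235). For choroid plexus, camera called the list without ICH+P7C3-A20 3 (median 1.63, adjusted p = 0.0121) and sham 2 (median 1.97, adjusted p = 0.0408). Of 9 ependymal genes, edgeR called 0 (0 adjusted over the list alone, 0 at unadjusted p under 0.05, 0 by DESeq2), median log2 change 0.10 (camera adjusted p = 0.428). Their mean was 0.08 and the test pointed down. For ependymal genes, camera called the list without ICH+P7C3-A20 2 (median -1.20, adjusted p = 2.41e-04). Against sham, camera called 24 of 37 lists, 17 up and 7 down, 5 of them also with an estimated correlation, and fry called 20. Of 4115 annotation terms, 431 were enriched among higher genes, led by inflammatory response (89 of 281 genes, hypergeometric adjusted p = 8.61e-38), and 13 among lower genes, led by regulation of postsynaptic membrane potential (7 of 45 genes, hypergeometric adjusted p = 0.00110).

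Values of some genes are uncertain because reads may be split with other genes. Over 50% of the transcript of Apoc2, Ccl21d, Hba-a1, Hba-a2, Lilr4b, Lilrb4a, Lyz2 and Phf11b matches another gene over at least 200 bases at 95% identity or more, and a smaller part for Cdkn1a, Csf3r, Cxcl16, Hnrnpa3, Itgax, Ly6c2, Mt2, Mx1, Nptxr, Pycard, Rarb and Slc32a1. Exons of Apoc2, Hnrnpa3, Lilr4b, Lilrb4a, Nexn and Nptxr overlap another gene on the same strand. Whether counting used strand is not given in the sources used here, so values of Acp5, Ano3, Baiap3, Cdkn1a, Ch25h, Col4a1, Cp, Cxcl10, Cxcl16, Grin1, Il1b, Irf7, Lilrb4a, Mt2, Nlrc5, Oasl1, Plk1, Pycard, Rarb, S1pr3, Slc32a1, Tagln, Tap1 and Tgm1, whose exons overlap a gene on the opposite strand, are uncertain too.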

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

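The blocks on mitochondrial share, the removal of mitochondrial genes, leaving out both libraries that stand apart, and annotation terms from other calls were chosen after seeing the data. Named called genes had 15 to 22 alternatives and called lists 12 to 13, which leave out other filters, DESeq2, limma other than quantile-normalized, the compared groups alone and mitochondrial gene removal. Over those run, no named called gene reversed, and 98 of 137, 54 of 103 and 41 of 82 named called genes and 10 of 23, 7 of 22 and 5 of 24 called lists kept their call in ICH against sham, ICH+P7C3-A20 against ICH and ICH+P7C3-A20 against sham. ICH against sham (5701 genes) gave, with higher and lower genes in brackets where either moved by over 1.5 times, 3073 (1683 and 1390) with an FPKM of at least 5, where fewer genes are tested, 2384 (2083 and 301) with a 2-fold minimum, 3760 (2530 and 1230), 3760 (2521 and 1239) and 3739 (2493 and 1246) with limma on FPKM and pseudocounts of 1, 0.5 and 0.1, and 4075 to 5561 without each library. ICH+P7C3-A20 against ICH (1914) gave 817 (107 and 710) with a 2-fold minimum, 3532 (1355 and 2177) with DESeq2, 1332 (549 and 783) with an FPKM of at least 5, 1498 (258 and 1240), 1438 (258 and 1180) and 1229 (228 and 1001) with limma at these pseudocounts, 5452 (1340 and 4112) with array weights, 3143 (1226 and 1917) with a block on mitochondrial share, and 571 to 1954 without each library. ICH+P7C3-A20 against sham (1165) gave 622 (514 and 108) with an FPKM of at least 5, 718 (705 and 13) with a 2-fold minimum, 2109 (1558 and 551) with DESeq2, 408 (385 and 23), 477 (450 and 27) and 532 (504 and 28) with limma at the 3 pseudocounts, 525 (416 and 109) with quantile normalization, 2774 (1745 and 1029) with array weights, 2222 (1661 and 561) without ICH+P7C3-A20 1 and sham 3, 1690 (1272 and 418) with the mitochondrial block, and 538 to 1434 without each library. With only the compared groups the counts were 5735, 2375 and 435 (393 and 42). With an estimated correlation 10, 7 and 5 lists were called. The share moved back was 96.9% to 99.1% without each library, and 94.7%, 96.4% and 95.8% with ICH 1, 2 and 3 held out. Annotation terms in ICH+P7C3-A20 against sham went from 444 to 229 with limma calls. The interferon list in ICH+P7C3-A20 against sham reversed, to a median of 0.0628, without ICH+P7C3-A20 1 and sham 3 (camera adjusted p = 0.964, over alternatives 0.0102 to 0.964). Except where given, the cause was not tested. Depth limits folds of genes at 0 in a group to lower bounds, and fitted changes of genes near 0, such as Kap in sham, are no bounds.

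Replicate numbers did not pair samples: same-number deviations correlated at -0.13 to 0.09. ICH 3 and ICH+P7C3-A20 2, under 12% mitochondrial, reached 0.19. The replicate block gave 5326, 1697 and 944 genes, 24, 23 and 24 lists and 98.5% moved back.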

Other observations

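The shares below, and the tests of injured tissue, of resting astrocytes, of ICH+P7C3-A20 1 and of the Hnrnpa3 family in ICH+P7C3-A20, were chosen after the results were seen. ICH+P7C3-A20 libraries kept part of the ICH rise. Over all genes called higher in ICH, the median share was 31.3 ± 13.4% (mean ± SD over 3 libraries). Interferon response genes kept -6.43 ± 7.43%, MHC class I genes 12.3 ± 11.3%, MHC class II genes 14.6 ± 4.69% and monocyte and macrophage markers 21.5 ± 7.90%. Haem and iron handling genes kept 28.0 ± 15.0%, reactive astrocyte genes 31.0 ± 12.1%, endothelial genes 41.8 ± 13.2% and homeostatic microglia markers 42.6 ± 19.6%.

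Of the lists, interferon genes kept the lowest share of the ICH rise, -37.8 percentage points from all raised genes. The SD, 6.46 over 3 ICH+P7C3-A20 libraries, leaves out spread in ICH and sham. If ICH+P7C3-A20 libraries only held less of a uniform injured tissue, all lists would keep an equal share. The gap argues against that as the whole cause. A single ICH library did not carry the interferon rise. The median log2 rise was 1.68, 1.16 and 1.32 without ICH 1, 2 and 3 (spread 0.267). An effect of P7C3-A20 on interferon signalling, or a difference in timing or injury between mice, may explain the gap and was not tested.

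Many immune and reactive glial genes were lower in ICH+P7C3-A20 than in ICH. Resting astrocyte markers had a median log2 change of 0.0120 (standard error 0.130 over members, 1 rose and 2 fell), by which more neuronal tissue cannot be told apart, since it brings resting astrocytes of its own. ICH+P7C3-A20 1, the library that stood apart, was not the whole cause, since 683 genes were called lower without it, 678 of them among the 1324 called with it. A first test, in which 1324 of 1324 called genes stayed lower at an unadjusted p under 0.05 without it, was replaced because simulated data with the observed group means gave 99.95% to 100%. More neuronal tissue, a smaller injury and an effect of P7C3-A20 stay open and may each contribute.

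Hnrnpa3 was lower in both ICH groups than in sham, alone by -3.50 and -3.74 on the log2 scale. The summed counts of Hnrnpa3 and its copies (22 genes) changed by -0.277 ± 0.102 (standard error) in ICH. A shift of reads between copies by the estimate of counts may explain part of the fall there. Alone it would leave the sum unchanged, and the sum fell by more than its standard error. In ICH+P7C3-A20 the sum changed by -0.716 ± 0.140, more than such a shift as the whole cause allows. No biological explanation was tested.

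Of the 10 splits of the 6 libraries in each comparison, 1 gave as many genes as the real one, itself. The real splits called 5701, 1914 and 1165 genes with edgeR and the highest of the others 0, 1 and 0, with too few splits for a share under 0.05.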
